A study of Mus musculus with 7 samples.

How the data were processed

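The samples were EKLF ChIP-seq, input and RNA-seq libraries of sorted fetal liver progenitors and erythroblasts from mice with hemagglutinin-tagged Klf1 at embryonic stage E13.5. Per the labels, RNA was sequenced in paired reads of 51 bp, ChIP fragments of about 200 bp were selected, and input libraries served as background for peak calling. Per the labels, at least 3 independent sorts were made for each population. The submitters' processing notes name build mm9. The aligner, peak caller and read counter are not given in the sources used here.

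The deposited expression table is named as RPKM, but its values behave as a coverage signal per coding exon. Every value was a whole multiple of 1 step per column (100% within 0.01 of a whole multiple), with 1835 steps per unit in progenitors and 2151 in erythroblasts. The paired multiples had no common divisor in 61.3% of exons, near the 60.8% of random pairs, so no exon length had been divided out. The deposited coverage signal is therefore read as summed bases over a library total, and levels are compared for the same gene between stages, not between genes. If a step is 1 base, the lowest listed values stand for 28.8 and 33.7 reads. Library totals were not used to set a counting error, and the ratio of the steps was 1.17. Whether the erythroblast column pools both erythroblast libraries is not given in the sources used here, so the columns are printed as the authors' values with no SD or n.

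The deposited peak lists hold 1 pooled list per stage. Column 7 is read as the authors' fold enrichment, since it is never below 2.14, and column 8 as the authors' -log10 p, since it is never below 5. Column 9 was not used.

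Exon names carry RefSeq transcript accessions, matched to symbols through the RefSeq table of GRCm38.p6. Of 6853 transcripts 6772 matched. Coordinates from that table were not used, because only 7.61% of exon starts fell inside their gene there. For each gene 1 transcript was kept, that with the most listed exons, and its exons were summed. The result was 5214 items, of which 4 join genes with the same exon positions, and 5194 had at least 1 in at least 1 column. Differences are log2((erythroblasts + 1) / (progenitors + 1)), which understates changes of low genes. The planned model with a test needed a column per library and could not be used, so a fixed rule of at least 2-fold replaced it, as planned for that case. The SD over exons describes spread within a gene. Exons are not replicates.

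Named genes followed a rule set before the data were examined: Klf1 and Tfrc, the 10 largest rises and falls with at least 5 in the higher stage, up to 4 members past the rule and 1 or 2 of the best covered others per list, the 5 highest-ranked peaks per list and class, and peaks at Klf1, globin, E2f2, Gata1, Kit, Myb and Gata2 genes. Some items that the rule names are not reported here. The 17 gene lists were also set then. Median differences of lists were placed among 10000 random lists matched on 10 levels of mean coverage.

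Peaks were shared where they overlapped by at least 1 bp, and 1000 random placements kept each peak's width and chromosome. A gene had a peak where one lay between its first and last listed exon starts or within 5 kb. Since unlisted exons are missing from these spans, some 5' ends lie outside them. Shares carry Wilson 95% intervals, which cover counting error only. Fisher's exact test gave odds ratios over genes, and its p-values are not printed since genes are not replicates. The approximate 95% intervals of the odds ratios likewise cover counting error over genes only. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 were used.

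The steps were tested on simulated data. With erythroblast exons drawn from 5194 real genes and exon noise of log2 SD 0.65, the 2-fold rule recovered 72.7% of genes changed by 1.5 on the log2 scale, 92.7% of those changed by 2 and 97.5% of those changed by 3, and took in 2.30% of unchanged genes. This noise leaves out differences between libraries. Of 200 random lists of 14 genes 6.5% lay outside the central 95% of their matched lists.

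Alternatives were other pseudocounts, filters, scalings and gene summaries, other definitions of a shared peak, other windows and the higher-ranked peaks. Input libraries had no values used here. Sequence motifs and distances to transcription start sites were not analysed here.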

Results

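Chromatin immunoprecipitation sequencing (ChIP-seq) of the erythroid transcription factor EKLF (gene Klf1) and RNA sequencing were compared between 2 stages of red cell development in the fetal liver of mice at embryonic stage E13.5. The mice carried Klf1 with a hemagglutinin tag, a short peptide that lets an antibody against the tag pull down the factor. Cells were sorted by Ter119, an antigen of maturing red cells, and CD71, the transferrin receptor. Progenitors lacked Ter119, and erythroblasts carried both antigens. The 7 samples were 2 ChIP libraries, 2 input libraries used as background, and 3 RNA libraries, of which 2 came from erythroblasts. The deposited values gave 1 peak list and 1 column of exon coverage per stage, so no difference between the stages has a replicate check. The expression table held 30257 coding exon rows, each at or above 0.8 in both columns, and these gave 5194 genes. A gene silent in either stage was therefore not analysed here, and the lowest value stood for 1468 coverage steps in progenitors and 1721 in erythroblasts.

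The first comparison asked which genes differ in RNA coverage between erythroblasts and progenitors. Both listed globin items, 10 of 14 listed heme and iron genes and 11 of 12 listed membrane and skeleton genes were at least 2-fold higher in erythroblasts, while 8 of 15 ribosome biogenesis genes were at least 2-fold lower. The adult beta-globin genes Hbb-b2 and Hbb-bt, listed as 1 item because they shared their exon positions, went from 9.59 in progenitors to 1686 in erythroblasts, a log2 difference of 7.32. Gata1, the erythroid master regulator, went from 42.1 to 2845, a log2 difference of 6.05 with an SD of 0.72 over its 5 exons. Lyl1, a helix-loop-helix factor of early blood progenitors, went from 154 to 3.98, a log2 difference of -4.96 with an SD of 0.92 over 3 exons. Genes are said to have risen or fallen where they differed at least 2-fold. By that rule 794 of 5194 genes rose, 685 fell and 3715 did neither.

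The tag and sort markers were examined first. Tfrc, which encodes CD71, rose from 21.3 to 148, a log2 difference of 2.74, and all 9 listed exons were higher in erythroblasts. Klf1 had 73.9 in progenitors and 145 in erythroblasts, a log2 difference of 0.96 that stayed under the rule. Its 3 listed exons differed widely, from 1.43-fold to 8.49-fold, and the median of their log2 ratios, 1.30, would pass it.

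The 10 largest rises among genes with at least 5 in the higher stage included both globin items and Gata1. The others were Atp1b2 (log2 difference 5.36), which encodes a sodium pump subunit, Cpeb4 (4.97), an RNA-binding regulator of translation, Abcb10 (4.94), a mitochondrial transporter needed for heme synthesis, and Hebp1 (4.88), a heme-binding protein. Nxpe2 (4.80), the mitochondrial iron importer Slc25a37 (4.73), Arhgap23 (4.71) and the alpha-globin item Hba-a1/Hba-a2 (4.66) followed. Of these rises 4 rested on 1 listed exon, those of Hbb-b2/Hbb-bt, Cpeb4, Nxpe2 and Arhgap23. The 10 largest falls were led by Ripor1 (-5.33) and Zfp36l2 (-5.08), an RNA-binding protein that promotes mRNA decay. Lyl1, the leukocyte surface protein gene Spn (-4.68), the immediate early gene Ier2 (-3.95), Riox1 (-3.75), Nrros (-3.69), Apbb1ip (-3.57), the second transferrin receptor gene Tfr2 (-3.47) and Zfp36l1 (-3.24) followed. Of these falls 7 rested on 1 listed exon.

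**Figure D1:**
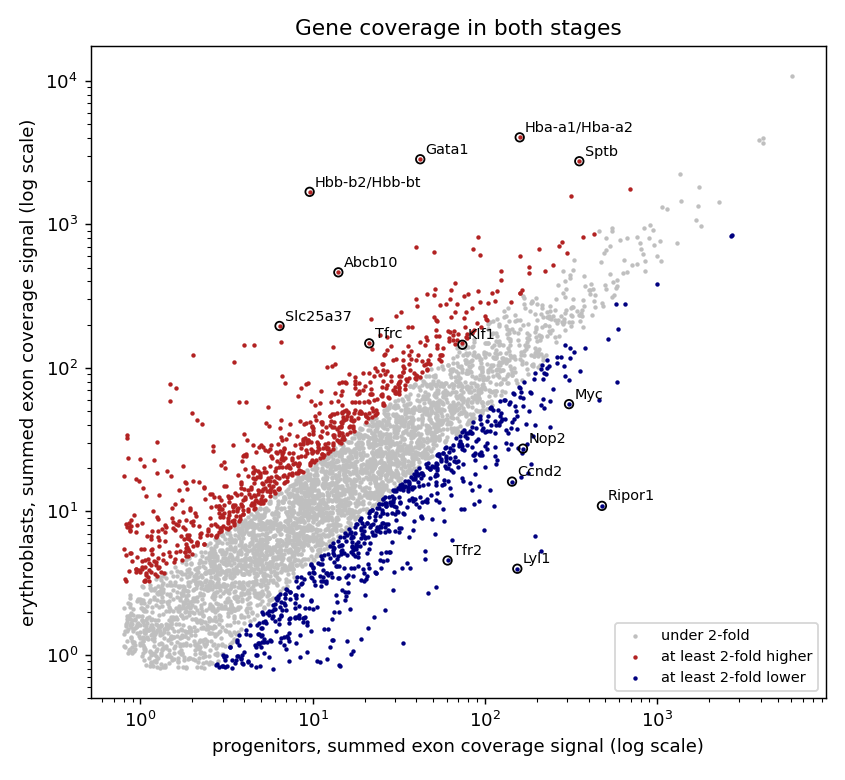
Summed exon coverage signal of 5194 genes in progenitors (horizontal axis, log scale) and erythroblasts (vertical axis, log scale), 1 point per gene, coloured by the 2-fold rule. Hbb-b2/Hbb-bt and Gata1 lie farthest above the diagonal, and Ripor1 and Lyl1 lie among the farthest below.

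Most heme synthesis and iron uptake genes rose. Of 17 genes on the list 14 were listed in the table, 10 rose, 1 fell and 3 did neither. Alad, an early enzyme of heme synthesis, rose from 50.5 to 642 with all 10 exons higher. Slc25a38, a mitochondrial glycine carrier, rose from 4.12 to 58.3. Tfr2 was the member that fell, from 60.6 to 4.54, on only 2 listed exons that are neighbours (starts at 138018686 and 138018894). Fech, which adds the iron in the last step of heme synthesis, had 169 and 279, under the rule. The list's median log2 difference was 2.11, above all 10000 random lists of the same size matched on mean coverage, as a description of these libraries.

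Red cell membrane and skeleton genes gave the same picture. Of 12 listed members 11 rose and none fell. The spectrin gene Sptb rose from 353 to 2756 and its anchor Ank1 from 91.0 to 817, each with all 31 exons higher. Add2, an adducin that helps join spectrin to actin in the membrane skeleton, rose from 85.2 to 674. Xk had 30.6 and 17.5, under the rule. The median log2 difference was 1.97, above all 10000 matched random lists.

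Among 14 listed erythroid transcription factor genes and the Epo receptor gene, 4 rose and 1 fell. Gata1, Lmo2 (22.03 to 65.8) and Foxo3 (65.2 to 157) were among those that rose, and Lyl1 fell. Zfpm1, a GATA1 cofactor, had 457 and 893, and Gfi1b, a repressor, had 405 and 325, both under the rule, though the median of the exon log2 ratios of Zfpm1 was 1.65. The median of 0.23 lay at percentile 80.3 of the matched lists. Of the 18 stem and progenitor genes only Myc and Runx1 were listed. Myc fell from 307 to 55.9, and Runx1 had 50.3 and 31.1.

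Cell cycle genes were examined as S phase and mitosis genes and as G1 regulators, and falls were seen only among the G1 regulators. Of 23 listed S phase and mitosis genes 7 rose and none fell, including the cyclin gene Ccne1 (9.78 to 58.5) and the replication licensing gene Cdc6 (35.8 to 142). The licensing genes Mcm3 (377 and 436) and Mcm5 (411 and 384) were under the rule, and the list's median of 0.28 lay at percentile 89.6. Of 10 listed G1 regulators 4 rose and 2 fell. The D-type cyclins went in opposite directions, as Ccnd2 fell from 143 to 16.1 while Ccnd3 rose from 124 to 407. The CDK inhibitor genes Cdkn1b (3.99 to 34.4) and Cdkn2c (4.51 to 17.0) rose. Cdk4 had 191 and 103, under the rule, which the median of its exon log2 ratios (-1.02) would pass. The median of 0.13 lay at percentile 65.1.

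The lists of autophagy and terminal maturation and of ribosome biogenesis lay on opposite sides of their matched lists. Of 12 listed maturation genes 7 rose, 5 did neither and none fell. The survival gene Bcl2l1 rose from 5.48 to 53.7 and the ubiquitin ligase gene Trim10 from 2.63 to 26.3, while the autophagy kinase gene Ulk1 had 59.8 and 46.9. The median of 1.29 lay at percentile 99.98. All 15 ribosome biogenesis genes were listed, 8 fell, 7 did neither and none rose. Nop2, an rRNA methyltransferase, fell from 166 to 27.3, Bop1 from 87.4 to 22.9 and Nop56 from 120 to 41.2. Ncl, which encodes nucleolin, had 712 and 523, under the rule. The median of -1.01 lay at percentile 0.03.

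A fixed selection of 22 genes published as dependent on EKLF was also examined, and not all such genes. Of these 14 were listed, of which 9 rose, 1 fell and 4 did neither. Alad, Ank1 and Add2 were among the rises, and Tfr2, with 2 listed exons, was the fall. Cd24a had 154 and 78.2, a log2 difference of -0.97 under the rule that passed it with globins removed (-1.03) and by exon median (-1.01). The median of 1.88 lay above all 10000 matched lists, and this list shares members with the heme and membrane lists. Of the 8 listed housekeeping genes 1 (Hprt, 5.14 to 1.92) fell, though its 2 exons went opposite ways and their median log2 ratio of -0.98 would not pass, and Actb had 903 and 994. No gene of the hepatocyte, macrophage, granulocyte and mast cell, B lymphoid or endothelial and stromal lists was listed. The megakaryocyte list had 1 listed member, Gp1ba, which rose from 9.35 to 31.6.

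**Figure D2:**
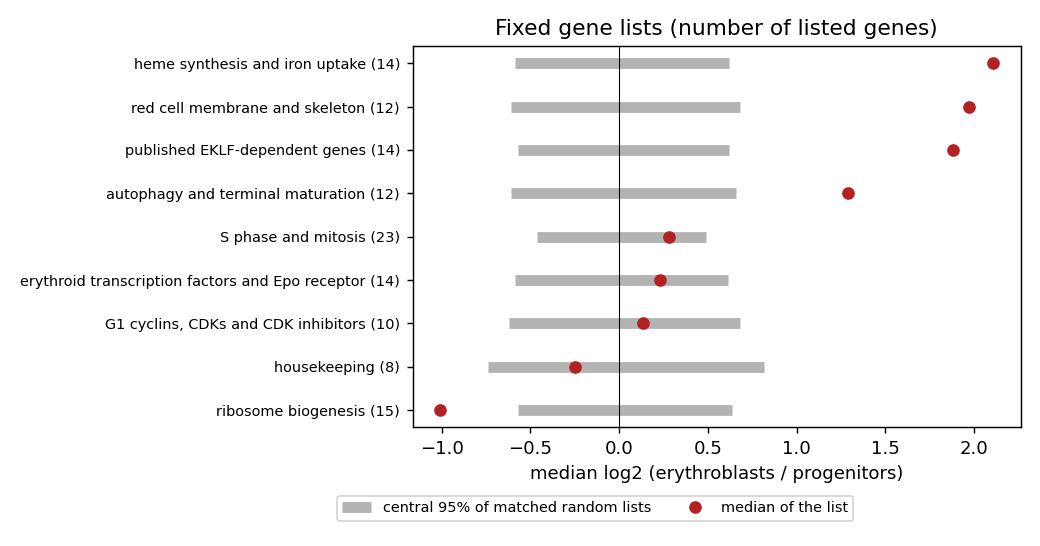
Median log2 difference (erythroblasts over progenitors) of each fixed list with at least 3 listed genes (points), with the central 95% of 10000 random lists matched on mean coverage (bars). The heme, membrane, EKLF-dependent and maturation lists lie above their bars, ribosome biogenesis lies below at -1.01, and the other 4 lists lie inside.

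The second comparison asked where EKLF was bound in each stage and how many sites were shared. Erythroblasts had 19353 peaks and progenitors 7358. The alpha-globin, beta-globin and Klf1 genes had strong peaks in the erythroblast list that no progenitor peak overlapped. At alpha-globin a peak on chromosome 11 from 32195322 to 32200936 (build mm9 throughout) had an enrichment of 45.4 and ranked 56 in the erythroblast list, and another from 32182487 to 32188033 had 30.3. Each covered a listed coding exon of Hba-a1/Hba-a2. At beta-globin a peak on chromosome 7 from 110956855 to 110963335 covered the listed exon of Hbb-b2/Hbb-bt with an enrichment of 20.7. At Klf1 a peak on chromosome 8 from 87425111 to 87427800 covered the starts of the first and second listed exons with an enrichment of 22.7. Enrichments and ranks are the authors' values and are read within 1 list only.

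A weak peak downstream of Klf1 was in both lists, from 87431782 to 87433388 in progenitors and from 87431681 to 87433353 in erythroblasts. E2f2, a cell cycle regulator bound by EKLF in earlier work, had 1 progenitor peak at its first coding exon, shared with erythroblasts, and 2 further erythroblast peaks inside the gene. The stronger of those, on chromosome 4 from 135733009 to 135735104, had an enrichment of 23.2. Gata1 had no peak in or within 5 kb of its listed exons in either list. Kit, Myb and Gata2 had no listed exon and were not located here.

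**Figure D3:**
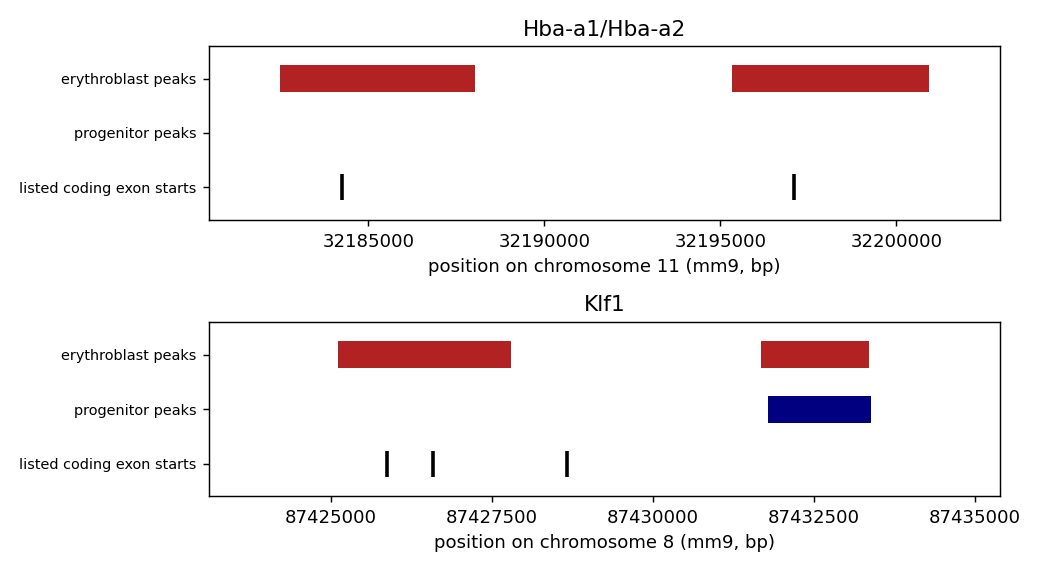
Peaks of the erythroblast and progenitor lists at Hba-a1/Hba-a2 (chromosome 11) and Klf1 (chromosome 8), drawn to scale in mm9 base pairs, with listed coding exon starts as ticks. Both alpha-globin peaks and the Klf1 peak from 87425111 have no progenitor counterpart, while the peak downstream of Klf1 appears in both lists.

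In all, 5956 progenitor peaks (80.9%, Wilson 95% interval 80.0 to 81.8%) overlapped an erythroblast peak by at least 1 bp, and 5977 erythroblast peaks (30.9%, 30.2 to 31.5%) overlapped a progenitor peak. Random placement of the erythroblast peaks within their chromosomes gave a mean of 219 overlapped progenitor peaks and at most 269 in 1000 placements (one-sided permutation p = 0.001, the smallest that 1000 placements can give). Placements were uniform along each chromosome and did not keep the nearness to exons that both lists have. The p-value therefore says only that the lists overlap more than uniformly placed peaks would. Sharing followed rank. In the highest-ranked 10% of the progenitor list 97.3% of peaks were shared, against 63.4% in the lowest-ranked 10%, and the erythroblast list went from 68.0 to 9.92%. With the 3679 highest-ranked peaks of each list, 41.2% of progenitor peaks were shared, so the share depends on the lengths of the lists compared.

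**Figure D4:**
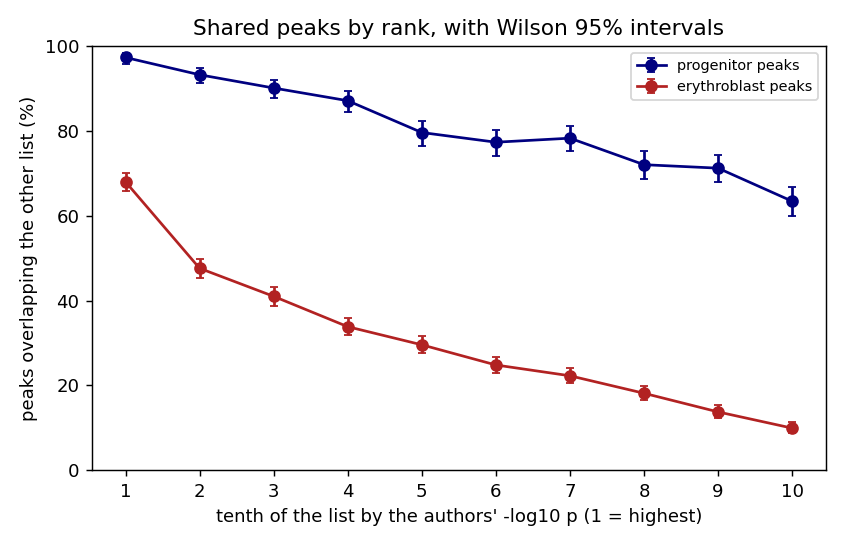
Percent of peaks overlapping the other list (vertical axis) in successive 10% bins of each list ranked on the authors' -log10 p (horizontal axis, 1 highest), with Wilson 95% intervals. Sharing falls from 97.3 to 63.4% over the progenitor list and from 68.0 to 9.92% over the erythroblast list.

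Many of the highest-ranked peaks of both lists lay around clustered histone genes. Of the 50 highest-ranked peaks 24 in progenitors and 27 in erythroblasts lay on chromosome 13 between 21632881 and 24276101, a window that holds 6 listed histone genes and extends beyond them on both sides. Of the 100 highest-ranked it was 28 in each list. The highest-ranked progenitor peak, from 22131754 to 22136492, covered the listed exon of the histone gene H4c9 with an enrichment of 70.9. The next 4 lay on chromosome 1 from 24618015 to 24623943, on chromosome 13 from 21899684 to 21907716 and from 21922713 to 21927997, and on chromosome 3 from 96040667 to 96045224. The 5 highest-ranked erythroblast peaks lay on chromosome 13 from 21825835 to 21828328, from 21840989 to 21842972, from 23851660 to 23854842 and from 22125948 to 22129263, and on chromosome 3 from 96040438 to 96045431, the last with an enrichment of 255. All 10 were shared. The 5 progenitor peaks, and the erythroblast peaks ranked 2 to 5, had the same -log10 p of 310. Their order therefore followed the enrichment, which was used to break ties. Among erythroblast-only peaks the highest-ranked, on chromosome 11 from 102207595 to 102227624, was 20.03 kb wide with an enrichment of 43.8. The nearest listed gene was Ubtf at 29.9 kb, whose next protein-coding neighbour in the order of the GRCm38.p6 annotation is Slc4a1, the red cell anion exchanger. Other high-ranked erythroblast-only peaks lay on chromosome 2 from 52551112 to 52559110, on chromosome 17 from 39979355 to 39986556, on chromosome 7 from 67001942 to 67043095 and on chromosome 14 from 70022491 to 70039761, all over 40 kb from a listed gene's exons. Their enrichments were 9.46, 2.94, 5.58 and 23.3, against a median of 9.31 over the erythroblast list, since rank followed the -log10 p. The enrichment of 2.94 was near the lowest of that list, 2.40, and the peak on chromosome 7 was 41.2 kb wide. A high rank is therefore not read as strong binding, and whether these peaks mark EKLF sites was not tested. The highest-ranked progenitor-only peak, on chromosome 5 from 43623224 to 43627271, ranked 119. The next ones lay on chromosome 8 from 24132989 to 24134853, 40.6 kb from a listed exon of Ank1, and on chromosome 19 from 46130329 to 46132339, 4.76 kb from Pprc1. Those on chromosome 11 from 98634121 to 98637430 and on chromosome 6 from 22305436 to 22307132 lay 8.53 kb from Thra and 2162 kb from Ndufa5, the nearest listed gene, respectively.

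Distances to transcription start sites were not analysed here, so location was described against listed coding exons. In progenitors 13.1% of peaks (12.3 to 13.9%) lay within 1 kb of a listed coding exon start, and in erythroblasts 7.91% (7.54 to 8.30%), against 2.09 and 1.99% in randomly placed peaks. Peaks lay toward the 5' ends of genes. Of 652 listed first coding exons of forward-strand genes 49.5% (45.7 to 53.4%) had a progenitor peak within 1 kb and 73.0% (69.5 to 76.3%) an erythroblast peak. Of 1512 listed last coding exons of reverse-strand genes these shares were 4.83% (3.86 to 6.03%) and 8.13% (6.86 to 9.62%).

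The third comparison asked whether genes with a peak differ in expression. Of the 2 globin items both had an erythroblast peak and no progenitor peak in or within 5 kb of their listed exons. So did 4 of 14 heme and iron genes (Cpox, Slc25a37, Slc25a38 and Slc25a39), 4 of 12 membrane genes (Ank1, Gypc, Xk and Ermap) and Lmo2 among the transcription factors. These classes depend on the window, as a progenitor-only peak lay 40.6 kb from a listed exon of Ank1. Of the heme, membrane and transcription factor genes, 5, 2 and 7 had peaks in both lists and 4, 6 and 6 had none. Over all genes 27.1% had peaks in both lists, 19.4% in erythroblasts alone and 49.7% in neither. At Slc25a37 a peak on chromosome 14 from 69857643 to 69864249 had an enrichment of 17.0. Peaks were also found at genes that fell, as Myc and Ccnd2 had erythroblast-only peaks. Alad had a progenitor peak and no erythroblast peak within this window. Of 23 S phase and mitosis genes 14 had peaks in both lists and 6 in erythroblasts alone. The counts for both lists and erythroblasts alone were 6 and 2 of 12 maturation genes, 5 and 3 of 15 ribosome biogenesis genes, 5 and 2 of 10 G1 regulators, 7 and 2 of 14 EKLF-dependent genes, and 4 and 2 of 8 housekeeping genes.

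Over all 5194 genes, 1410 had peaks in both lists, 1007 in erythroblasts alone, 197 in progenitors alone and 2580 in neither. Unlisted exons are missing from the gene spans, so peaks at 5' ends beyond the 5 kb window were not counted. Of listed first coding exons of forward-strand genes 73.0% had an erythroblast peak within 1 kb. The genes with neither may therefore include genes with a peak at their 5' end, which also limits the odds ratios. Likewise, genes with an erythroblast peak alone may include genes with a progenitor peak at their 5' end. Of the same first coding exons 49.5% had a progenitor peak within 1 kb. An erythroblast peak was present at 47.1% (43.7 to 50.6%) of the 794 genes that rose and at 46.4% (45.0 to 47.9%) of the others, an odds ratio of 1.03. It was present at 43.1% (39.4 to 46.8%) of the 685 genes that fell and at 47.1% of the others, an odds ratio of 0.85 with an approximate 95% interval of 0.72 to 1.001. That ratio was 1.10 (0.85 to 1.42) within 50 kb and 0.78 (0.67 to 0.91) with a pseudocount of 0.1, and intervals also lay below 1 with median-ratio scaling and quantile normalization. Genes are not replicates, so these intervals describe counting error and do not test a difference between the stages. A progenitor peak was present at 29.8% of genes that rose and 30.2% of genes that fell. Genes with an erythroblast peak alone had a median log2 difference of 0.078, at percentile 98.8 of random lists matched on mean coverage, where the random median was 0.0045. This small difference was not kept in every setting. With a window of 50 kb the median was 0.058, at percentile 83.1, and at the first coding exons of 643 forward-strand genes it was -0.068, at percentile 13.96. In those 643 genes with the window of 5 kb it was -0.030, at percentile 48.6. Genes with peaks in both lists had a median of 0.035, at percentile 92.3, and genes with none had 0.011, at percentile 2.64.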

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

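The settings without wide peaks, histone genes or sex chromosomes, those based on exons and those matched on span or erythroblast coverage were chosen after seeing the data. With pseudocounts of 0.1 or 0.5, another filter or another scaling, counts of genes that rose stayed between 735 and 940 and of genes that fell between 633 and 808. The median of exon log2 ratios gave 996 and 758. Quantile normalization gave 735 and 747, and removal of globins 735 and 756. Genes with at least 2 exons all on one side numbered 513 and 350, 863 in all, since fewer genes qualify. No named gene past the rule changed sign. Pseudocounts, filters and exons on one side could not change a sign. The scalings shifted the median of all genes little, by -0.056 with globins removed. With the median of exon log2 ratios Mcm5 (0.23), Ulk1 (0.13) and E2f4 (0.29), under the rule and below 0 in the report's summary, lay above 0. The 9 lists with at least 3 listed genes stayed inside or outside the central 95% of their matched lists as reported, except that housekeeping had too few genes for exons on one side. The G1 regulators' median was -0.32 with the filter at 5 and with exons on one side.

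Of progenitor peaks 59.7% were shared with midpoints within 250 bp, 71.2% in the 50% highest-ranked peaks and 41.2% in equal numbers. Of erythroblast peaks these shares were 22.7, 27.1 and 41.3%, and 31.7% without X and Y. Within 5 kb of an exon start lay 20.03% of progenitor and 12.6% of erythroblast peaks, and within 1 kb 16.04 and 9.86% of the 50% highest-ranked. Within 50 kb, 3509 genes had peaks in both lists and 487 in neither, since the window is wider, and with the 50% highest-ranked peaks 735 had both.

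The median of 0.078 for genes with an erythroblast peak alone left the outer range within 50 kb (0.058) and with quantile normalization (0.017), and was below 0 in 643 forward-strand genes with a listed first coding exon, at -0.068 (percentile 13.96, 192 genes) within 1 kb of that exon and at -0.030 (percentile 48.6, 182 genes) with the window of 5 kb, both inside the central 95%. Against lists matched on erythroblast coverage the same 0.078 lay at percentile 74.2, which says nothing of stability, since that coverage is part of the difference. The odds ratio of an erythroblast peak at genes that fell was 1.10 (0.85 to 1.42) within 50 kb, 0.92 (0.77 to 1.10) with the 50% highest-ranked peaks, 0.83 (0.71 to 0.97) with median-ratio scaling, 0.82 (0.70 to 0.96) with quantile normalization and 0.78 (0.67 to 0.91) with a pseudocount of 0.1. The cause was not tested.

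Limma without the trend, leaving out each erythroblast library and camera were not run, because each stage had 1 column. Motif settings and windows around transcription start sites were not run, for want of a genome of the build. No paired analysis was possible because the columns carry no replicate number.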

Other observations

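The tests of both patterns weighed here were set before their own results were seen. The test by strength replaced one that compared enrichments between the lists, and another such test, of peaks in histone gene clusters, was dropped, both after sharing by rank and the enrichments of shared peaks had been examined. The limit for calling the difference by strength undecided, and the reading of the match on erythroblast coverage as undecided, came after the results. By the rules first set, both results would have been read in favour of the explanations tested. These were that the progenitor list missed sites by strength alone, and that peaks follow the level of transcription in erythroblasts. Peaks on the sex chromosomes were unevenly spread. Chromosome X held 348 progenitor and 1298 erythroblast peaks, 4.73 and 6.71% of each list, and 7.68% of erythroblast-only peaks. Chromosome Y held 2 and 31. Of 6 listed histone genes on chromosome 13 none passed the 2-fold rule. H2ac10 (844 and 476 in progenitors and erythroblasts) and H2ac8 (852 and 559) had lower coverage in erythroblasts. H4c9 (3.54 and 5.45), H4c4 (5.27 and 6.82), H1f4 (0.99 and 2.46) and H2bc4 (8.08 and 8.87) had higher coverage. The progenitor value of H1f4 lay near the lowest listed value of 0.80.

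Erythroblast peaks outnumbered progenitor peaks, and 13376 of them had no progenitor counterpart. If the weaker ones were background calls placed at random, they would lie near exons as often as random peaks. Of the lower-ranked 50% of erythroblast-only peaks 4.19% lay within 1 kb of a listed coding exon start, against at most 2.41% in 1000 placements, which argues against random background as the source of all of them. Background that favours open chromatin was not tested and may still contribute. If the progenitor list missed sites by strength alone, peaks of the same rank would be missing equally often at genes that rose and fell, and the difference was 6.73 percentage points (bootstrap interval -1.29 to 13.1), too wide to decide. A change in binding between stages stays open, untested.

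Genes with an erythroblast peak alone had slightly higher erythroblast coverage. The difference was set against lists matched on mean coverage from the start, so that match was not a new test of coverage level. With a further match on the span of listed exons it lay at percentile 99.5. That argues against this span alone as the source of the difference. Whether peaks follow the level of transcription in erythroblasts stays open. The difference lay at percentile 74.2 of lists matched on erythroblast coverage, but that coverage is the numerator of the difference, and the match also moved genes with peaks in both lists from percentile 92.3 to 0.2 and genes with none from 2.64 to 100. In 643 forward-strand genes with a listed first coding exon the median was -0.068 within 1 kb of that exon and -0.030 with the window of 5 kb, so the small difference was not seen in that smaller set under either window. No biological explanation was tested.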
